A study of Homo sapiens with 29 samples.

How the data were processed

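RNA was measured in 29 samples of cultured human endothelial cells, as polyadenylated RNA isolated with a Qiagen RNeasy Plus kit and prepared with a KAPA stranded mRNA-seq kit per the labels' protocols, whose text also names a TruSeq v2 kit. HUVEC grew in EGM-2 medium and HCMEC/D3 in EndoGRO-MV with FGF2, per the labels. The labels give the Y27632 dose as 10 mM for 18 h, which is high for this inhibitor and in doubt, and the term "3D" in some labels is not explained in the sources used here. Groups were taken from the labels alone. Where the sample names gave no usable replicate number, one was assigned by the order of the samples. The 2 treated control libraries carry the same replicate label in their names and became replicates 1 and 2 in this way. Prefixes of the sample names were taken as runs, although no source used here says what they mark. They are written here as A to D for HUVEC (2, 11, 7 and 1 libraries) and E and F for HCMEC/D3 (4 libraries each).

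The HUVEC values were raw read counts per gene, deposited by the authors, in a table of 28441 entries. The HCMEC/D3 values were RPKM, computed by the authors and deposited with 2 decimals, for 20500 entries, and counts of these samples were not used here. The authors' deposited tables of comparisons give fold changes, computed by the authors and deposited as log2 values per the file headers for HCMEC/D3 and for CCM3 with Y27632, and as logs of no named base elsewhere. Their p-values were deposited by the authors adjusted as a false discovery rate. The ratio columns of fold change deposited beside them equal the exponential of these logs, as natural logs would give, so the base is in doubt and the ratio columns were not used. Per the submitters' processing notes, reads were aligned to hg19 and Picard 1.88, SAMtools 1.2 and DESeq2 were used, without the role or order of each. The aligner, the counting tool and its strand setting are not given in the sources used here, so reads of overlapping genes cannot be assigned with certainty.

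From the counts, 27 entries whose gene names had been turned into dates and 1 entry of unnamed genes, which held 0.180 to 0.235% of the reads, were left out, and 28413 entries were kept. The 50 most abundant genes held 10.8 to 14.5% of the counts of a library. HUVEC counts were fitted with edgeR 4.0.16 in R 4.3.3 as 21 libraries in 10 groups of hairpin and treatment, with TMM scaling, edgeR's filter on low counts (16602 genes kept), robust quasi-likelihood tests and a Benjamini-Hochberg adjusted p under 0.05. The common BCV was 0.279. For shCCM2 the coefficients of its hairpins were averaged, and the averaged Y27632 effect was the mean over the 5 constructs. Standard errors of edgeR log2 fold changes were the size of the change over the square root of its F statistic. HCMEC/D3 values were fitted as log2(RPKM + 0.5) with limma 3.58.1 (trend and robust options), for the 11949 genes of at least 1 RPKM in at least 2 libraries, and 11069 to 11478 genes per library reached 1 RPKM.

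Each loss was compared with its control, with and without Y27632 in HUVEC, with the other losses, and in HUVEC across treatments as the effect of Y27632 and its interaction with each loss. The 23 gene lists were tested with limma's camera on moderated statistics with a correlation of 0.01 between genes, adjusted over the lists of a comparison. Counts of list members that pass are given after adjustment over all genes, and also adjusted over the list alone. The same test with a correlation estimated from the residuals was run beside it. A list needed at least 3 tested members, which left 22 in HCMEC/D3, where the leukocyte list was not tested. Named genes follow a rule: the CCM genes, CCM2L, MAP3K3, SMURF1, RHOA, KLF2 and KLF4 always; the 8 called genes with the highest and the 8 with the lowest log2 fold change (4 and 4 in other comparisons) among those with a mean of at least 5 CPM or 2 RPKM over the libraries compared and no overlap between the groups; and up to 4 called members per list with the smallest p. Some genes that the rule names are not reported here, genes at 0 in every library of a group are not discussed except DARC in HCMEC/D3, and genes outside the rule were named after their values were seen: HNRNPH2 and RPL36A-HNRNPH2, CPA3, the shared genes and the genes called in both cell types.

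The groups, comparisons, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. Those alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter at 1 CPM, fits of only the compared libraries, run as a block, pseudocounts of 0.1 and 1, quantile normalization, estimated correlation in the list tests, and each library left out in turn. After the data were seen, fits were added with the untreated controls summed, without run A, with construct and run as a block for the Y27632 effect (each pair also left out in turn), and with any knockdown against control. Whether runs pair samples was checked by correlating deviations from group means. Overlap of calls was compared with independent lists of the same sizes and, in HUVEC, with 20 simulations of unchanged groups against the same controls.

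The tests were tried on simulated data with the fitted spread and sizes. A change of 2-fold was called in 17.9, 20.9 and 19.4% of changed genes for CCM1, CCM2 and CCM3 loss in HUVEC, and one of 4-fold in 83.3, 87.9 and 71.2%, so most changes near 2-fold are missed there. In HCMEC/D3 a 2-fold change was called in 91.0, 71.6 and 74.6%, and for the averaged Y27632 effect in 85.1%. False calls made up 1.92 to 9.74% of simulated calls. Of 100 random lists 2 had an unadjusted p under 0.05, which does not test correlated lists. The untreated HUVEC controls had a BCV of 0.0225, far below the common 0.279, so the simulated shares may not hold against them. Sex-linked transcripts were not examined, and no variants were called.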

Results

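Polyadenylated RNA of human endothelial cells was sequenced in 29 samples. Of these, 21 came from HUVEC, primary endothelial cells of the umbilical vein. They were labelled as control or with a short hairpin RNA against KRIT1 (CCM1), CCM2 or PDCD10 (CCM3). Loss of any of these genes in endothelial cells gives rise to cerebral cavernous malformations, clusters of dilated and leaky brain vessels. The control group held 2 libraries, which the sample names give only as control. The CCM1 hairpin shCCM1-2 held 3, the CCM2 hairpins shCCM2-1 and shCCM2-5 held 2 each, and the CCM3 hairpin shCCM3-2 held 3. CCM1 and CCM3 had 1 hairpin each, so effects of these hairpins on other genes cannot be told apart from loss of the target. Further libraries came from cells given Y27632, an inhibitor of the kinases ROCK1 and ROCK2, for 18 h at a labelled 10 mM, a dose in doubt: 2 of the control, 2 of shCCM1-2, 1 of shCCM2-1, 2 of shCCM2-5 and 2 of shCCM3-2. Total counts per HUVEC library ran from 8980571 to 47569443, with a median of 19800972. The other 8 samples came from HCMEC/D3, an immortalised line of human brain microvascular endothelial cells, as the unedited line (WT) and as knockouts of CCM1, CCM2 or CCM3 (1KO, 2KO and 3KO), with 2 libraries each. Both libraries of a knockout carry the same code in their names, so each knockout may be a single clone, and a difference from WT cannot be told apart from a difference between clones. Their depth is unknown, because the values were RPKM. By its title the series asked how the CCM proteins and the kinase MEKK3 act on the ubiquitin ligase SMURF1 and on RhoA in endothelial cells. The design compared the loss of each CCM gene with its control, with the other losses, and with and without ROCK inhibition.

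Each target gene was lowest in the libraries labelled for it. KRIT1 was 8.68 to 18.7 CPM (counts scaled to library size) in the 5 shCCM1 libraries, treated ones included, against 25.9 to 35.3 CPM in the 4 control libraries. CCM2 was 15.0 to 30.1 CPM in the 7 shCCM2 libraries against 70.5 to 79.7 CPM in the controls. PDCD10 was 2.44 to 3.74 CPM in the 5 shCCM3 libraries against 31.2 to 36.6 CPM in the controls. In HCMEC/D3, KRIT1 was 2.70 and 3.07 RPKM in 1KO against 10.2 and 10.4 RPKM in WT. CCM2 was 7.0 and 11.6 RPKM in 2KO against 31.6 and 31.7 RPKM in WT, and PDCD10 was 0.860 and 0.900 RPKM in 3KO against 46.8 and 51.7 RPKM in WT. All 3 fell in the untreated comparisons by edgeR (HUVEC) and limma (HCMEC/D3): the log2 fold change ± standard error was −1.05 ± 0.21 and −1.68 ± 0.15 for KRIT1, −1.87 ± 0.18 and −1.76 ± 0.21 for CCM2, and −3.52 ± 0.21 and −5.17 ± 0.14 for PDCD10, HUVEC first.

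**Figure D1:**
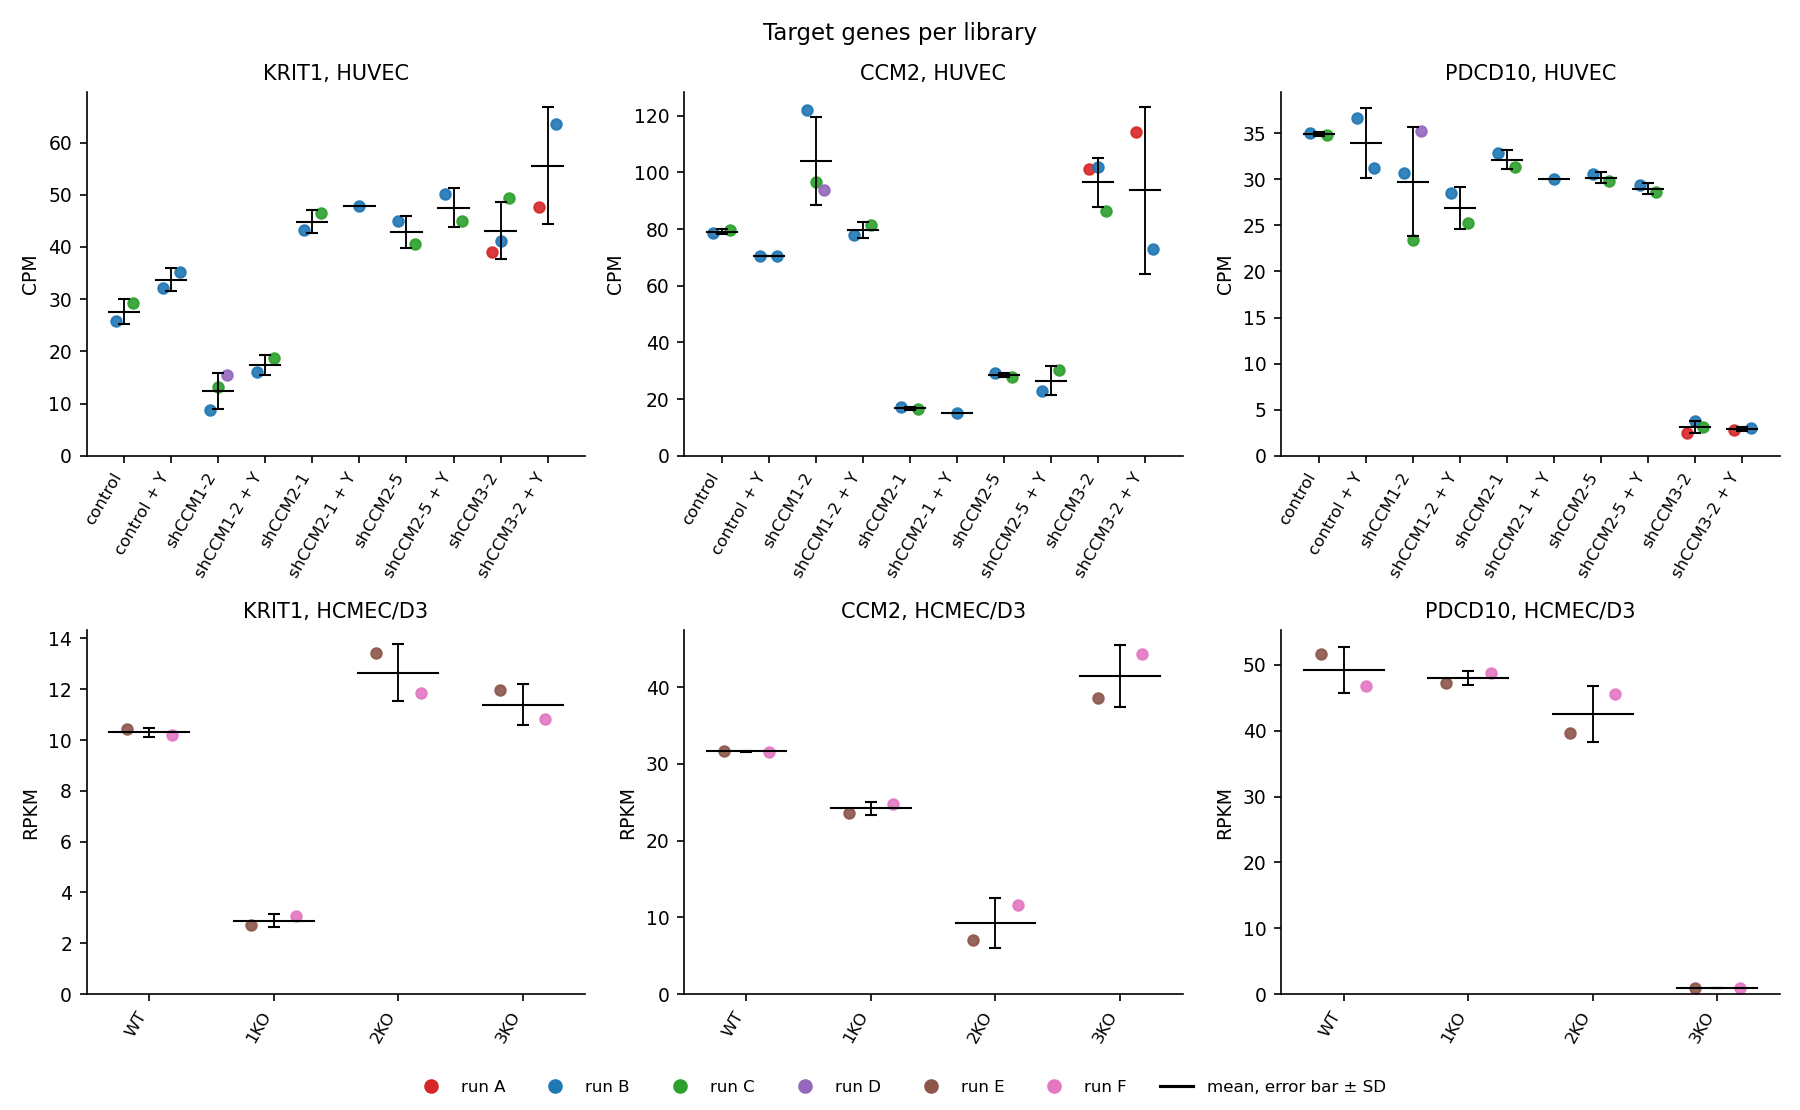
Levels of KRIT1, CCM2 and PDCD10 in each library, in CPM for HUVEC (upper panels) and RPKM for HCMEC/D3 (lower panels); points are libraries coloured by run, horizontal lines group means and error bars SD, and "+ Y" marks Y27632. All 5 shCCM1 libraries lay below the 4 controls for KRIT1, all 7 shCCM2 libraries for CCM2 and all 5 shCCM3 libraries for PDCD10.

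The untreated control libraries limited every comparison against them. They came from different runs, yet their biological coefficient of variation (BCV) was 0.0225, against at least 0.108 in the other 209 pairs of HUVEC libraries and at least 0.149 in the 11 other pairs of one group from different runs. Their counts still differed by more than sampling noise, with a median chi-square 1.60 times that expected, and they were kept as 2 samples, as designed. Where they were summed to 1 sample, a choice made after the data were seen, the counts of genes are given beside the main ones. No source used here says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

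Loss of CCM1 in HUVEC was accompanied by higher levels of the flow-responsive transcription factors KLF2 and KLF4. KLF2 was 571 ± 150.1 CPM (SD, n = 3) against 158 ± 1.92 (n = 2), a log2 fold change of 1.97 ± 0.32 (edgeR, adjusted p = 0.0125). KLF4 was 119 ± 30.7 against 22.4 ± 1.76 CPM, a rise of 2.52 ± 0.40 (adjusted p = 0.0118). Their targets rose with them: NOS3, the endothelial nitric oxide synthase, by 1.36 ± 0.26 and THBD, the anticoagulant receptor thrombomodulin, by 2.75 ± 0.56. In the list of the KLF2, KLF4 and ERK5 axis 5 of 25 members rose and none fell (11 and 0 adjusted over the list alone; camera adjusted p = 8.33e-08, and adjusted p = 0.00639 with an estimated correlation). The highest and lowest changes named in this report are those among called genes past the limits on mean level and overlap of the naming rule. For CCM1 loss the largest rises of this kind were those of CYP26B1, which degrades retinoic acid (6.31 ± 1.15), the prostaglandin transporter SLCO2A1 (4.98 ± 0.73), the water channel AQP3 (4.94 ± 0.84) and PI16 (4.83 ± 0.84). Next came the sialyltransferase ST6GALNAC1 (4.79 ± 0.86), the complement regulator properdin CFP (4.06 ± 0.70), the chemerin receptor CMKLR1 (3.73 ± 0.84) and PTHLH (3.60 ± 0.68). ITGB4, the laminin-binding integrin beta-4, rose by 2.73 ± 0.36, from 122 ± 3.74 to 747 ± 51.6 CPM, the sialomucin EMCN by 1.99 ± 0.42 and the hyaluronan receptor LYVE1 by 3.16 ± 0.65.

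Genes lower in shCCM1 than in control included the chemokine receptor CXCR4 (−2.79 ± 0.34; 12.3 ± 1.41 against 92.3 ± 0.230 CPM), placental growth factor PGF (−1.87 ± 0.32), and PHGDH, the first enzyme of serine synthesis (−3.01 ± 0.54). Lower as well were the potassium channel subunit KCNAB1 (−2.81 ± 0.62), the metalloprotease TLL1 (−2.78 ± 0.62), AIM1 (−2.72 ± 0.60), endothelial lipase LIPG (−2.44 ± 0.54) and HMGCS1 of cholesterol synthesis (−1.55 ± 0.27). The T cell receptor features TCRVB (−2.74 ± 0.51) and BV03S1J2 (−2.80 ± 0.47) were lower too, but they are aggregate features that share sequence with others, and their values are uncertain. All 25 members of the cell cycle list had a negative log2 fold change. Their median was −1.40, and the list passed the test as lower although no member did alone (adjusted p = 2.22e-06, and adjusted p = 0.712 with an estimated correlation). The endothelial identity list passed as higher with 1 of 20 members called (4 up and 1 down adjusted over the list alone; adjusted p = 0.0264, and adjusted p = 0.364 with an estimated correlation). CCM2L, a paralogue of CCM2, had a log2 fold change of 1.01 (adjusted p = 0.145), RHOA of 0.35 (adjusted p = 0.540), SMURF1 of −0.07 and MAP3K3, which encodes MEKK3, of 0.25, and none of them passed the test. In all, edgeR called 167 of 16602 genes, 89 higher and 78 lower, and 2327 had an unadjusted p under 0.05. DESeq2 called 622. With the controls summed no gene passed (1116 at an unadjusted p under 0.05), although all 167 kept their sign and an unadjusted p under 0.05. Without control replicate 1 or without control replicate 2 the count was 0, and without shCCM1-2 replicate 3 it was 63.

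With CCM2 knocked down, KLF2 rose from 158 ± 1.92 (n = 2) to 468 ± 31.3 CPM (SD, n = 4), by 1.56 ± 0.30 on the log2 scale (edgeR, adjusted p = 0.0178), and KLF4 by 2.41 ± 0.38. In the list of the KLF2, KLF4 and ERK5 axis 8 of 25 members rose and none fell (15 up and 2 down adjusted over the list alone; adjusted p = 4.83e-06, and adjusted p = 0.0495 with an estimated correlation). Among them were NOS3 (1.24 ± 0.25) and the aggrecanases ADAMTS1 (2.81 ± 0.64) and ADAMTS9 (1.54 ± 0.32), which cleave matrix proteoglycans. Genes stimulated by interferon were lower: IFI6 fell from 1118 ± 114 to 15.7 ± 6.94 CPM (−6.19 ± 1.19). IFI44L (−4.55 ± 1.10), the ubiquitin-like protein ISG15 (−3.18 ± 0.72) and IFI27 (−2.54 ± 0.62) fell too. In that list 7 of 24 members fell (15 adjusted over the list alone; adjusted p = 4.35e-11, and adjusted p = 0.385 with an estimated correlation). Of the 2 controls treated with Y27632, 1 lay 2.06 log2 units below the other in the mean of this list. Of the NF-kB and inflammation list 3 of 19 members fell (10 adjusted over the list alone; adjusted p = 4.83e-06, and adjusted p = 0.385 with an estimated correlation). They were the chemokines CCL2 (−5.04 ± 1.05) and IL8 (−2.44 ± 0.64) and the leukocyte adhesion molecule E-selectin, SELE (−3.95 ± 0.85).

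The largest rises with CCM2 loss were those of the growth factor binding protein IGFBP5 (7.04 ± 1.62; 213 ± 292 CPM, SD over 4 libraries that differed widely), the metalloprotease inhibitor TIMP3 (5.73 ± 1.45), PI16 (4.55 ± 0.82) and the tetraspanin TSPAN7 (4.31 ± 1.09). They were followed by the potassium channel KCNN4 (4.27 ± 1.10), the glycoprotein hormone STC1 (4.09 ± 0.79), SLCO2A1 (4.04 ± 0.69) and CMKLR1 (3.83 ± 0.82). Other low values were those of MS4A6A (−3.75 ± 0.76), FLJ41200 (−3.34 ± 0.63), TLL1 (−3.08 ± 0.57) and LIPG (−2.74 ± 0.50). The list of SRF and MRTF actin targets (1 of 22 members fell, the LIM protein FHL2 at −1.34 ± 0.29; 5 adjusted over the list alone) passed as lower (adjusted p = 2.20e-04, and adjusted p = 0.299 with an estimated correlation). So did that of the unfolded protein and p53 stress responses (3 of 19 fell, TRIB3 −1.01, CHAC1 −1.98 and XBP1 −0.74; 4 adjusted over the list alone), with adjusted p = 0.00675, and adjusted p = 0.494 with an estimated correlation. No other list passed. In the RhoA and ROCK list 2 of 30 members rose, the myosin light chain kinase MYLK (0.97 ± 0.21) and the KRIT1-binding receptor HEG1 (1.69 ± 0.40). Of the others 1 fell, the myosin light chain MYL12B (−1.31 ± 0.20), with 3 up and 5 down adjusted over the list alone. Of the endothelial to mesenchymal transition list 3 of 20 fell (among them SNAI1 −1.59 and LY6E −2.28), and of the BMP and TGF-beta targets 2 of 17 (TGFBI −2.66 and ID3 −0.95). In the tip cell list 2 of 20 members rose, STC1 and VEGFC (1.92), and 2 fell, CXCR4 (−2.49) and PGF (−2.09), and of the ECM protease list 3 of 21 rose. A few members moved in the lists of junctions (ITGB4 2.06 and MLLT4 1.09), Notch signalling (DLL1 2.00 and HES4 −1.71), arterial, venous and lymphatic fate (LYVE1 2.74 and CXCR4), endothelial identity (EMCN 1.96), glycolysis and hypoxia (PFKFB3 −0.82) and cholesterol synthesis (DHCR7 −0.74). No member was called in the lists of YAP and TAZ targets (0 of 17), basement membrane (0 of 25), cell cycle (0 of 25) or markers of smooth muscle cells and pericytes (0 of 7), fibroblasts (0 of 9), leukocytes (0 of 5) and epithelium (0 of 6).

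RHOA (0.07, adjusted p = 0.880), SMURF1 (0.22, adjusted p = 0.628), MAP3K3 (−0.28, adjusted p = 0.531) and CCM2L (0.86, adjusted p = 0.113) did not pass the test with CCM2 loss. In all, edgeR called 575 genes, 216 higher and 359 lower, with 3742 at an unadjusted p under 0.05. DESeq2 called 1448, with 720 higher and 728 lower, and edgeR 1304 with run as a replicate block and 902 with only the compared libraries. With the controls summed CCM2 alone passed (1778 at an unadjusted p under 0.05), although 574 of the 575 genes kept their sign and an unadjusted p under 0.05. The count was 1 without control replicate 1 or control replicate 2, 38 without shCCM2-1 replicate 1, 152 without shCCM2-5 replicate 1 and 309 without shCCM2-5 replicate 3. The 2 hairpins against CCM2 differed in 1 gene by edgeR, the transferrin receptor TFRC (−3.32 ± 0.33; 13.1 CPM with shCCM2-1 against 119.7 with shCCM2-5), with 793 genes at an unadjusted p under 0.05, and in none without shCCM2-1 replicate 2. Of the lists 7 passed between the hairpins with no member called, cell cycle as higher with shCCM2-1 and as lower ECM proteases, basement membrane, KLF axis, junctions, endothelial to mesenchymal transition and BMP targets, at adjusted p = 9.34e-06, 0.00104, 0.00941, 0.0248, 0.0254, 0.0297 and 0.0301, and adjusted p = 0.599, 0.0708, 0.599, 0.453, 0.453, 0.430 and 0.599 with an estimated correlation.

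**Figure D2:**
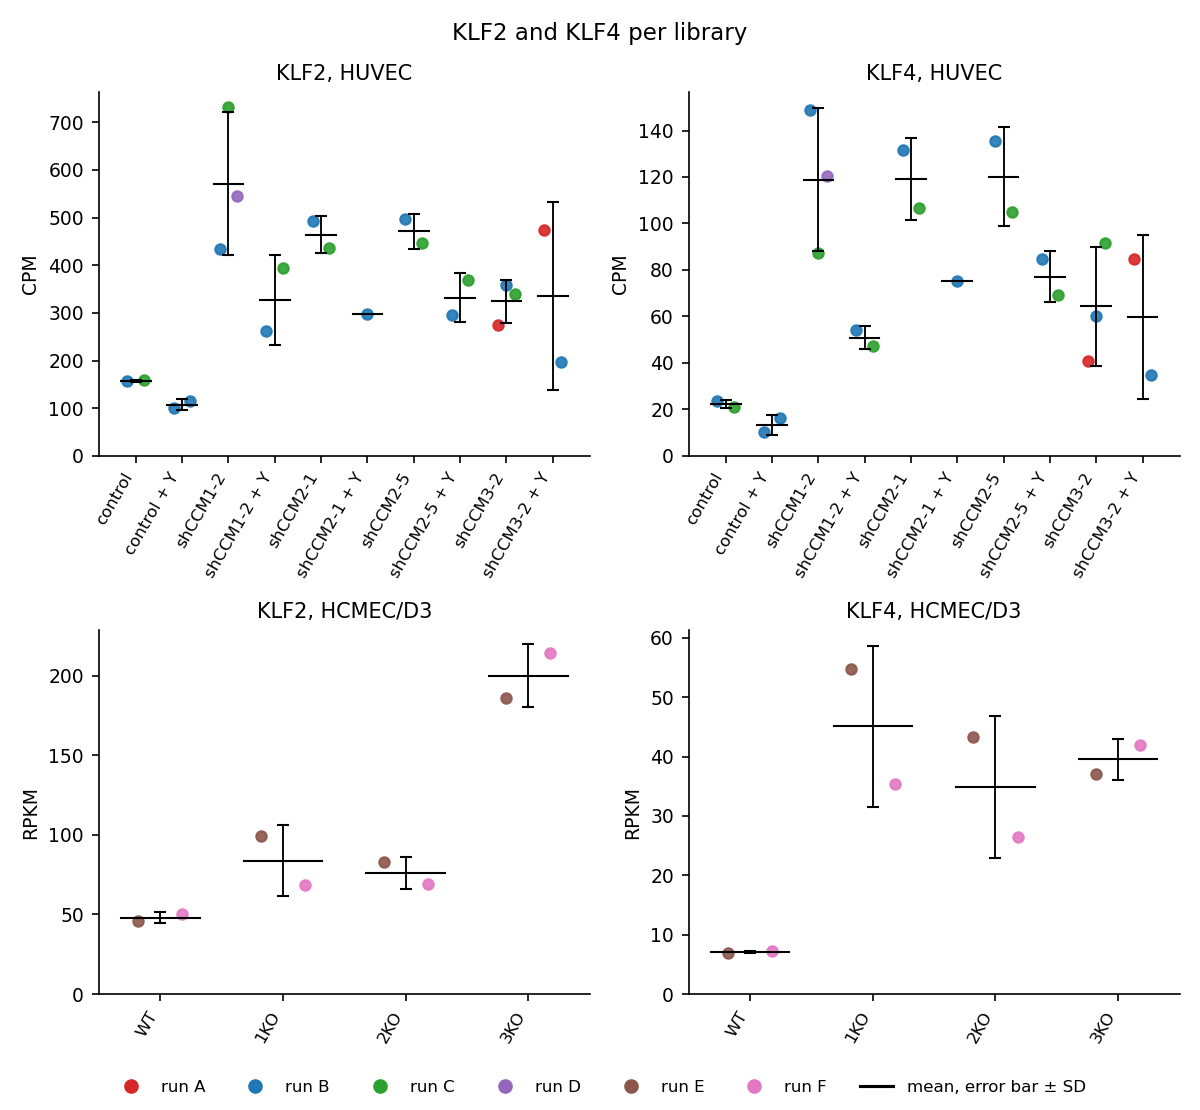
KLF2 and KLF4 in each library, in CPM for HUVEC (upper panels) and RPKM for HCMEC/D3 (lower panels); points are libraries coloured by run, lines group means and error bars SD. Untreated controls averaged 158 CPM of KLF2 and 22.4 CPM of KLF4, and all untreated knockdown libraries lay above both.

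With CCM3 knocked down, the largest rises among called genes past the same limits were those of IGFBP5 (7.33 ± 1.66; 184 ± 249 CPM, SD over 3 libraries), CYP26B1 (5.98 ± 1.14), the Duffy chemokine receptor DARC (5.61 ± 1.29) and TSPAN7 (5.33 ± 1.16), followed by CMKLR1 (5.13 ± 0.88), SLCO2A1 (4.58 ± 0.72), the lectin FCN3 (4.30 ± 0.92) and PI16 (4.23 ± 0.82). Beside PDCD10 itself, the lowest values were those of IFI6 (−6.61 ± 1.37), IL1RL1, the receptor of interleukin 33 (−3.59 ± 0.84), TLL1 (−3.51 ± 0.63), the collagen COL3A1 (−2.68 ± 0.42; 5.21 against 33.7 CPM) and PLEKHA4 (−2.68 ± 0.39). The uncertain features TCRVB (−2.49 ± 0.50) and BV03S1J2 (−2.40 ± 0.46) were lower too. KLF2 was 324 against 158 CPM, a log2 fold change of 1.02 ± 0.31 that missed the threshold (edgeR, adjusted p = 0.0939). So did KLF4 (1.49 ± 0.38, adjusted p = 0.0584) and CCM2L (1.29, adjusted p = 0.0554). This group includes the run A library, whose label is in doubt, as described below. It had 273.5 CPM of KLF2 and 40.9 of KLF4, and its partner labelled as treated had 474.7 and 84.7. An exchange of labels would raise the KLF2 and KLF4 means of the untreated group. The list of the KLF2, KLF4 and ERK5 axis passed as higher, with 3 of 25 members called (11 up and 2 down adjusted over the list alone; adjusted p = 6.71e-05, and adjusted p = 0.121 with an estimated correlation). These were NOS3 (1.22 ± 0.26), ASS1, which feeds nitric oxide synthesis with arginine (2.40 ± 0.51), and the prostaglandin synthase PTGDS (4.46 ± 0.93).

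Of the interferon list 1 of 24 members fell with CCM3 loss (15 adjusted over the list alone; adjusted p = 3.72e-11, and adjusted p = 0.380 with an estimated correlation), while the treated controls differed by 2.06 in the mean of this list. The cell cycle list passed as higher, with 24 of 25 members positive and none called (median 0.67, adjusted p = 0.0152, and adjusted p = 0.729 with an estimated correlation). The stress response list passed as lower with none of 19 called (2 down adjusted over the list alone; adjusted p = 0.00797, and adjusted p = 0.387 with an estimated correlation). Members called in lists that did not pass included CXCR4 (−1.68), PGF (−1.38), TGFB1 (−1.08), the calcium-binding protein S100A4 (2.82), hexokinase HK2 (−1.72), the basement membrane linker NID1 (1.25), ITGB4 (2.37), DLL1 (1.46) and MYL12B (−0.97). RHOA (−0.12), SMURF1 (−0.02) and MAP3K3 (0.10) were not called. HNRNPH2, an RNA-binding protein, fell (−1.54 ± 0.17), and its neighbouring feature RPL36A-HNRNPH2 shares its reads, so neither is certain. In all, edgeR called 245 genes, 100 higher and 145 lower, with 2954 at an unadjusted p under 0.05. DESeq2 called 958, with 499 higher and 459 lower, and edgeR 1068 with only the compared libraries. With the controls summed 4 passed, PDCD10, HNRNPH2, RPL36A-HNRNPH2 and the carboxypeptidase CPA3 (1414 at an unadjusted p under 0.05), although all 245 kept their sign and an unadjusted p under 0.05. The count was 4 without control replicate 1 or control replicate 2, 95, 22 and 105 without shCCM3-2 replicates 2, 3 and 1, and 94 without the run A libraries.

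The 3 losses shared part of their calls. In all 3 comparisons 26 genes rose and 13 fell, and no gene was called in all 3 with mixed signs. Among those that rose were NOS3, ITGB4, CYP26B1, SLCO2A1, CMKLR1, PI16, AQP3, CFP, the heparan sulphatase SULF2, the ephrin EFNB1, the chloride channel protein CLIC2 and the endothelial chaperone HSPA12B. Among those that fell were CXCR4, PGF, TLL1, the prohormone convertase PCSK1, the receptor EPHB6 and BPGM, which makes the allosteric effector of haemoglobin. All 3 comparisons used the same controls. Independent lists of these sizes would share 0.00697 genes up and 0.0147 down, and unchanged groups simulated against the same controls shared at most 1 gene in 20 simulations. No simulated comparison called more than 2 genes, so the simulations give no chance value for lists as long as the real ones. A split of the controls would leave 1 library on each side, so part of the excess may come from the shared controls, and with the controls summed no gene was shared. The count of 39 became 0 without control replicate 1 or control replicate 2, 15 without shCCM2-1 replicate 1, 25 without shCCM2-5 replicate 3, and 25, 9 and 23 without shCCM3-2 replicates 2, 3 and 1.

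**Figure D3:**
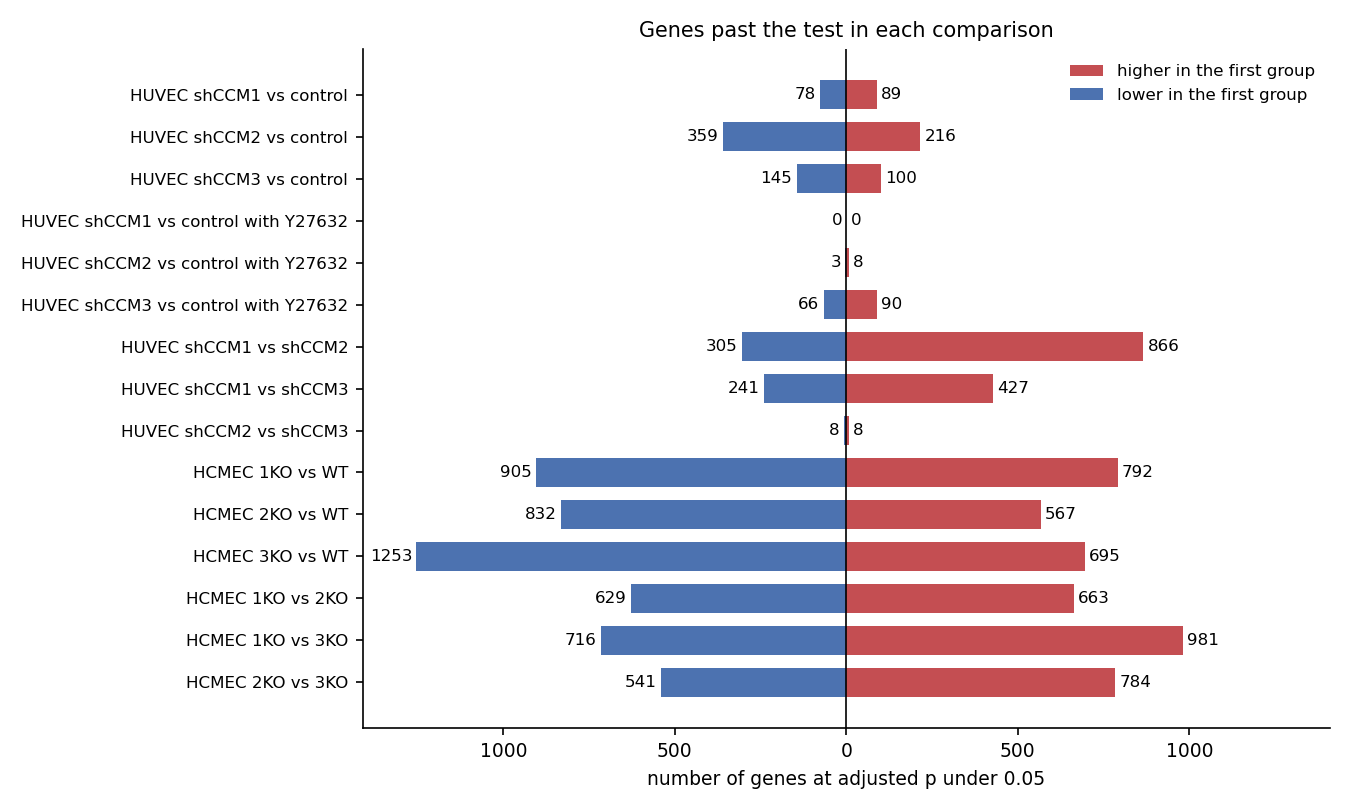
Number of genes at an adjusted p under 0.05 in each comparison, higher in the first group to the right and lower to the left (edgeR for HUVEC, limma for HCMEC/D3). Counts ran from 0 for shCCM1 against control with Y27632 to 1253 genes lower in 3KO than in WT.

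Under Y27632 the same losses were compared with treated controls. With CCM3 loss PDCD10 fell (−3.48 ± 0.25), and KLF2 (1.70 ± 0.33), KLF4 (2.22 ± 0.41) and CCM2L (1.71 ± 0.35) passed the test. Of the 2 treated libraries, that of run A had 474.7 CPM of KLF2 and that of run B 196.4, and the labels of the run A pair are in doubt. An exchange there would change these values, and without run A the count of called genes fell to 2. Also past the test were CMKLR1 (6.84 ± 1.01), PI16 (4.73 ± 0.87), the LIM domain protein LMO7 (4.04 ± 0.44), ITGB4 (2.68 ± 0.37), NOS3 (1.28 ± 0.27), and ASS1 (2.46 ± 0.53). Further rises were those of NID1 (1.76 ± 0.30), HEG1 (2.07 ± 0.45), MYLK (1.07 ± 0.24) and the metalloprotease ADAM19 (1.84 ± 0.42). Lower were TLL1 (−3.28 ± 0.73), the cyclooxygenase PTGS1 (−2.76 ± 0.60), LRRC17 (−2.71 ± 0.58), COL3A1 (−2.40 ± 0.48) and the glycolytic enzymes HK2 (−1.59 ± 0.35) and PGK1 (−1.07 ± 0.24). The KLF axis list rose (5 of 25 members, 7 adjusted over the list alone; adjusted p = 3.26e-05, and adjusted p = 0.0301 with an estimated correlation). The glycolysis and hypoxia list fell (2 of 20 members, 4 adjusted over the list alone; adjusted p = 0.0220, and adjusted p = 0.0240 with an estimated correlation). Markers of fibroblasts fell as well (1 of 9 members, 4 adjusted over the list alone; adjusted p = 0.00664, and adjusted p = 0.0193 with an estimated correlation). With CCM2 loss CCM2 fell (−1.80 ± 0.20), and KLF4 (2.55 ± 0.40), CLIC2 (3.31 ± 0.40), the acid phosphatase ACP5 (2.54 ± 0.38), LMO7 (2.40 ± 0.40) and ITGB4 (2.16 ± 0.35) rose. KLF2 had 1.57 (adjusted p = 0.0763). With CCM1 loss no gene passed, and KRIT1 (−0.89, adjusted p = 0.777), KLF2 (1.66, adjusted p = 0.602) and KLF4 (2.00, adjusted p = 0.602) did not either.

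Of the gene lists under Y27632, that of the KLF axis passed as higher with CCM1 loss with no member called (6 up adjusted over the list alone; adjusted p = 7.88e-07, and adjusted p = 0.0240 with an estimated correlation), and with CCM2 loss with 1 of 25 (5 adjusted over the list alone; adjusted p = 1.36e-05, and adjusted p = 0.0637 with an estimated correlation). The interferon list passed as lower in all 3 with no member called, at adjusted p = 1.81e-12, and adjusted p = 0.292 with an estimated correlation for CCM1, adjusted p = 2.15e-08, and adjusted p = 0.395 with an estimated correlation for CCM2 and adjusted p = 2.25e-06, and adjusted p = 0.548 with an estimated correlation for CCM3. The 2 treated controls differed by 2.06 in the mean of this list. With CCM1 loss the lists of cell cycle (lower), cholesterol synthesis (lower) and junctions (higher) passed with no member called, at adjusted p = 1.81e-12, 0.0454 and 0.0377, and adjusted p = 0.292, 0.484 and 0.292 with an estimated correlation. With CCM2 loss the inflammation and SRF lists passed as lower with no member called, at adjusted p = 3.34e-04 and 1.65e-04, and adjusted p = 0.395 and 0.166 with an estimated correlation. With CCM3 loss the lists of junctions (1 of 20 members up, 5 adjusted over the list alone) and endothelial identity (0 of 20, 1 up adjusted over the list alone) passed as higher, at adjusted p = 0.00271 and 0.0432, and adjusted p = 0.0933 and 0.395 with an estimated correlation.

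By edgeR the treated comparisons called 0 genes for shCCM1 (632 at an unadjusted p under 0.05, 21 by DESeq2), 11 for shCCM2 (8 higher, 3 lower) and 156 for shCCM3 (90 higher, 66 lower). For the last 2 DESeq2 called 173 and 774, edgeR with run as a replicate block 2 and 314, and edgeR with only the compared libraries 0 and 515. The count for shCCM2 was 2 without control with Y27632 replicate 1 or 2, 3 without shCCM2-5 with Y27632 replicate 1 and 18 without shCCM2-1 with Y27632 replicate 3. The count for shCCM3 was 2 and 14 without control with Y27632 replicates 1 and 2, 3 and 96 without shCCM3-2 with Y27632 replicates 2 and 1, and 2 without the run A libraries. The interaction of each loss with Y27632, which tests whether the inhibitor changed its effect, called no gene by edgeR or DESeq2, with 193, 78 and 74 genes at an unadjusted p under 0.05 for CCM1, CCM2 and CCM3. In the interaction lists with no member called passed: interferon (lower), KLF axis (lower) and SRF (higher) for CCM1, at adjusted p = 1.39e-17, 0.00373 and 0.00379, and adjusted p = 0.332, 0.332 and 0.353 with an estimated correlation. For CCM2 these were cell cycle and interferon (both higher), at adjusted p = 2.25e-05 and 0.00353, and adjusted p = 0.9996 for both with an estimated correlation. For CCM3 they were RhoA and stress response (both higher), at adjusted p = 0.0409 and 0.0409, and adjusted p = 0.321 and 0.540 with an estimated correlation.

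The effect of Y27632 itself, averaged over the 5 constructs, called no gene either. KLF2 averaged −0.50 ± 0.15 and KLF4 −0.70 ± 0.18 on the log2 scale (edgeR, adjusted p = 0.660 for both). The cell cycle list passed as higher, with all 25 members positive (median 0.61; adjusted p = 5.97e-09, 0.645 with an estimated correlation). The interferon list passed as lower with all 24 members negative (median −1.03; adjusted p = 2.38e-11). Its median was −3.10 in shCCM1, −0.02 in shCCM2, −0.21 in shCCM3 and −0.81 in control, whose treated libraries differed by 2.06 in its mean. Lower too were the KLF axis (21 of 25 negative) and stress response lists (18 of 19), at adjusted p = 0.00148 and 8.69e-04. The lower lists had adjusted p = 0.460 with an estimated correlation. No member of these lists was called. By edgeR 1235 genes had an unadjusted p under 0.05 in the averaged effect, and 192, 1096, 297 and 75 in the control, shCCM1, shCCM2 and shCCM3 cells taken alone, none of which had a called gene. Lists that passed in single constructs at the preset correlation of 0.01 did not pass with an estimated one. DESeq2 called 41 genes in shCCM1 and none in the others or in the average, and without shCCM1-2 with Y27632 replicate 1 edgeR called 2 in shCCM1. The shCCM3 pair of run A moved against the others: KLF2 was 474.7 CPM with Y27632 and 273.5 without it in run A, but 196 and 359 in run B. When treated and untreated libraries of one construct and run were paired, a block chosen after the data were seen, edgeR again called 0 genes, 501 without that run A pair, and 0 when any of the other 7 pairs was left out.

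**Figure D4:**
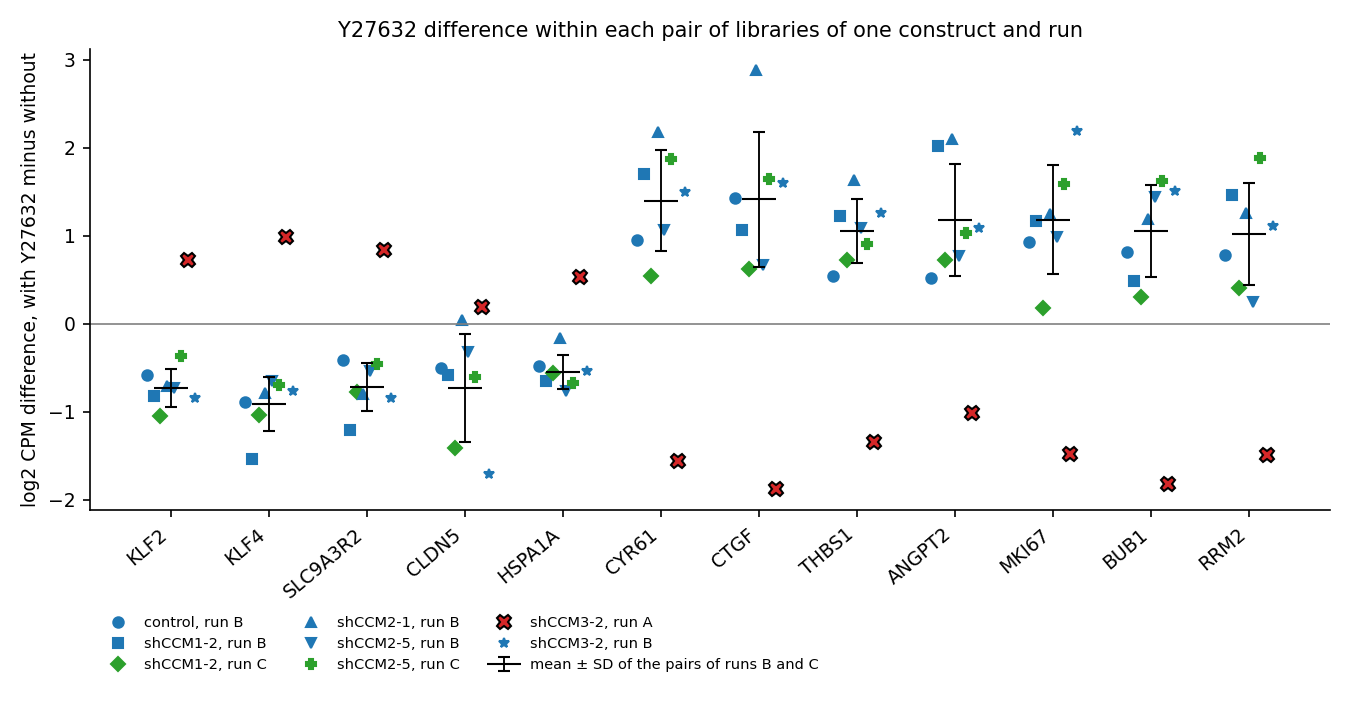
Difference in log2 CPM between the library with Y27632 and the one without it, for 12 genes, chosen from the fit without run A, and 8 pairs of one construct and run, of which the control pair holds 2 treated libraries and 1 untreated; black bars are the mean ± SD of the 7 pairs of runs B and C. The shCCM3 pair of run A (crosses) lay on the other side of 0 from that mean for each gene.

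Direct comparisons of the losses in untreated HUVEC asked where they differ. Between CCM1 and CCM2 loss the interferon-stimulated genes OASL (6.64 ± 1.32) and IFI6 (5.34 ± 1.12), the chemokine CCL2 (4.76) and the cytokine signalling inhibitor SOCS3 (3.52 ± 0.78) were higher with CCM1 loss. So were the adhesion molecule ICAM1 (2.81), TGFBI (2.37), the matrix cross-linker LOXL2 (1.42), the fibronectin receptor subunit ITGA5 (1.38), the myosin light chain MYL9 (1.64) and the small GTPases RND1 (2.23) and RHOC (0.90). Lower were the ion channels PIEZO2 (−2.72 ± 0.42) and KCNN3 (−2.19 ± 0.58), AIM1 (−2.69 ± 0.55), DNM3 (−1.91 ± 0.37), HMGCS1 (−1.70) and NOTCH2 (−1.21). Between CCM1 and CCM3 loss the interferon-stimulated IFI6 (5.76 ± 1.29), IFI44L (5.07 ± 1.22) and MX1 (5.07), the actin-binding TAGLN (2.83 ± 0.69) and COL3A1 (2.78 ± 0.40) were higher with CCM1 loss. The mitotic genes ASPM (−4.31 ± 1.07), DLGAP5 (−4.02 ± 1.06) and ANLN (−3.51 ± 0.87), AIM1 (−3.76 ± 0.58), the YAP target CTGF (−3.12 ± 0.76) and the lymphatic receptor FLT4 (−2.57 ± 0.60) were lower. Between CCM2 and CCM3 loss edgeR called 16 genes, among them beside the targets COL3A1 (2.22 ± 0.37), HNRNPH2 (1.47 ± 0.15), FKBP1B (−1.43 ± 0.25) and the YAP target ANKRD1 (−3.21 ± 0.54).

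The interferon list was higher with CCM1 than with CCM2 loss in 13 of 24 members (23 adjusted over the list alone; adjusted p = 1.86e-13, and adjusted p = 0.657 with an estimated correlation). Against CCM3 loss it was higher in 7 of 24 (20 adjusted over the list alone; adjusted p = 1.15e-12, and adjusted p = 0.553 with an estimated correlation). The cell cycle list was lower with CCM1 than with CCM3 loss, with 1 of 25 members called (20 adjusted over the list alone; adjusted p = 9.17e-12, and adjusted p = 0.553 with an estimated correlation). Also higher with CCM1 than with CCM2 loss were the lists of inflammation (6 of 19 members), SRF targets (5 of 22) and stress responses (2 of 19), and lower that of the cell cycle (0 of 25), at adjusted p = 3.05e-06, 0.0129, 0.0129 and 0.00529, and adjusted p = 0.657, 0.735, 0.735 and 0.806 with an estimated correlation. Between CCM1 and CCM3 loss the stress list was higher in 2 of 19 members (adjusted p = 0.0299, and adjusted p = 0.553 with an estimated correlation). Lists lower with CCM2 than with CCM3 loss, with no member called, were those of cell cycle, cholesterol synthesis, inflammation and SRF targets, at adjusted p = 6.48e-10, 9.01e-05, 1.40e-05 and 7.21e-04, and adjusted p = 0.525, 0.442, 0.448 and 0.442 with an estimated correlation. In the mean of the interferon list the 3 shCCM1 libraries stood apart from each other, from 3.59 to 7.47 log2(CPM + 1), with the highest in run B. The untreated shCCM2 and shCCM3 libraries ran from 3.17 to 3.95 and both untreated controls lay at 5.90. In all, edgeR called 1171 genes between CCM1 and CCM2 loss (866 higher, 305 lower), 668 between CCM1 and CCM3 loss (427 higher, 241 lower) and 16 between CCM2 and CCM3 loss (8 in each direction). In the same order DESeq2 called 2018, 1581 and 149, and edgeR with run as a replicate block 2270, 1378 and 6. Fitted with only the compared libraries, each of the first 2 called 1 gene. Without shCCM1-2 replicate 3 the first became 30 and the second 33. The first was also 40 without shCCM2-1 replicate 1, 31 without shCCM2-5 replicate 1, 616 without shCCM1-2 replicate 1 and 571 without shCCM2-1 replicate 2. The second was also 46 and 12 without shCCM3-2 replicates 2 and 3, and 10 without the run A libraries. The last was 169 without shCCM3-2 replicate 1, 5 and 4 without replicates 2 and 3 of that group, 6 and 5 without shCCM2-1 replicates 1 and 2, 4 and 6 without shCCM2-5 replicates 1 and 3, and 4 without the run A libraries. With the CCM2 hairpins pooled this comparison called 13 genes, while the same libraries split by run called 132. With run as a replicate block the comparison of 16 called 6. The comparisons with CCM3 loss hold the run A library labelled as untreated, whose label is in doubt.

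**Figure D5:**
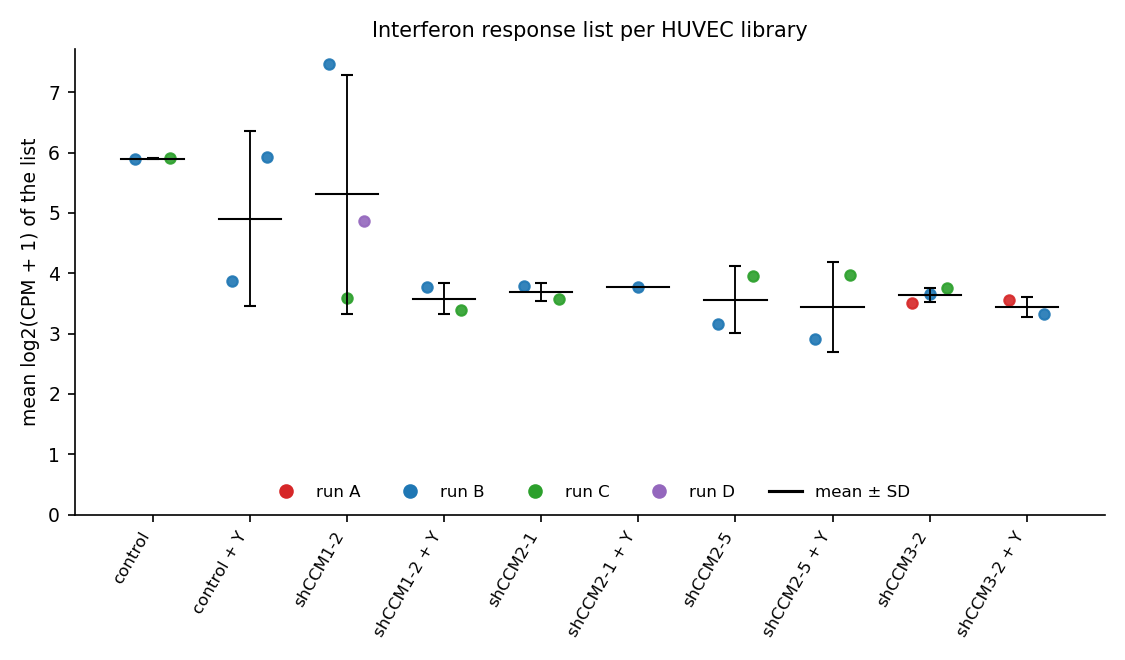
Mean log2(CPM + 1) of the 24 interferon response genes in each HUVEC library; points are coloured by run, lines are group means and error bars SD. Both untreated controls lay at 5.90, the treated controls at 3.88 and 5.93, and the shCCM1 libraries between 3.59 and 7.47.

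In HCMEC/D3 the knockout of CCM1 was accompanied by a rise of KLF4 (2.55 ± 0.26; 45.1 against 7.10 RPKM, n = 2 each; limma, adjusted p = 3.87e-04) and KLF2 (0.78 ± 0.20; 83.8 against 47.9 RPKM, adjusted p = 0.0342). THBD (3.36 ± 0.26), PTGDS (2.62 ± 0.52) and MEF2A (0.94 ± 0.18) of the same axis rose too. Of that list 7 of 19 tested members rose and none fell (10 adjusted over the list alone; adjusted p = 0.00133, and adjusted p = 0.0585 with an estimated correlation). All fold changes in this line are on the log2(RPKM + 0.5) scale, which understates changes of low genes. The largest rises were those of the matricellular protein POSTN (4.61 ± 0.16), FAM83A (4.16 ± 0.24), CD180 (3.77 ± 0.25), and SLCO3A1 (3.67 ± 0.26). The next were the protease inhibitor SERPINE2 (3.66 ± 0.37), the exchange factor ARHGEF4 (3.65 ± 0.17), PLVAP, the diaphragm protein of fenestrated endothelium (3.64 ± 0.20), and RIMS1 (3.60 ± 0.18). Among the lowest were the collagens COL1A2 (−5.14 ± 0.32; 0.680 against 40.7 RPKM), COL6A2 (−4.88 ± 0.29) and COL1A1 (−3.77 ± 0.21). Low as well were ARHGAP22 (−4.85 ± 0.15), UCHL1 (−4.22 ± 0.26), the transcription factor TAL1 (−3.98 ± 0.22) and the BMP antagonist GREM1 (−3.82 ± 0.29).

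Of the cholesterol synthesis list 9 of 17 members fell with CCM1 loss in this line and none rose, with INSIG1 at −2.57 ± 0.21 and FDFT1 at −1.26 ± 0.19 (13 adjusted over the list alone; adjusted p = 3.11e-07, and adjusted p = 0.233 with an estimated correlation). Of the ECM proteases 6 of 13 rose and 1 fell, with MMP2, a collagenase of basement membranes, at 3.05 ± 0.24 (7 and 1 adjusted over the list alone; adjusted p = 4.17e-04, and adjusted p = 0.0119 with an estimated correlation). The glycolysis and hypoxia list fell (1 up and 4 down of 20, with CA9 at −1.84 and ADM at −1.19; 2 and 5 adjusted over the list alone; adjusted p = 0.0160, and adjusted p = 0.0248 with an estimated correlation). The lists of endothelial identity (7 up, 2 down of 18; TEK 1.95, ESAM −2.18) and of arterial, venous and lymphatic fate (3 up, 1 down of 8; PDPN 2.13, SOX17 1.68) passed as higher at adjusted p = 0.00634 and 0.0131, and at adjusted p = 0.389 and 0.233 with an estimated correlation. Fibroblast markers (2 up, 2 down of 5) passed as lower (adjusted p = 0.00365, and adjusted p = 0.0508 with an estimated correlation). SMURF1 fell (−0.57 ± 0.16, adjusted p = 0.0434), as did the actin-regulating kinase LIMK1 (−1.06), MYLK (−1.17) and MYL9 (−1.26), while the RhoA list as a whole did not pass and RHOA had 0.21 (adjusted p = 0.409). Limma called 1697 of 11949 genes, 792 higher and 905 lower, with 337 and 524 genes without WT replicates 3 and 1 and 677 without 1KO replicate 1.

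In 2KO KLF4 was higher than in WT (2.18 ± 0.26; 34.9 against 7.10 RPKM), while KLF2 had 0.66 (limma, adjusted p = 0.0720). The largest rises were those of the tryptophan-degrading enzyme KYNU (5.10 ± 0.27), FAM83A (4.44 ± 0.24), DTX4 (4.03 ± 0.30) and GALNTL2 (3.72 ± 0.80; 41.1 ± 41.5 RPKM, SD, n = 2), followed by SERPINA1 (3.58 ± 0.70), the actin-capping TMOD1 (3.58 ± 0.51), MN1 (3.49 ± 0.32) and TNXB (3.40 ± 0.60). Of the genes named for 2KO, the fibrinogen chain FGG had the lowest fold change against WT (−6.98 ± 0.22; 0.235 against 89.7 RPKM), and other low values were those of PHGDH (−5.56 ± 0.23), the microfibril protein FBN2 (−5.07 ± 0.23), COL1A1 (−5.02 ± 0.21), the NADPH oxidase subunit CYBA (−4.94 ± 0.21) and GREM1 (−4.51 ± 0.29). Basement membrane genes fell in 9 of 22 members (1 up and 10 down adjusted over the list alone; adjusted p = 2.12e-06, and adjusted p = 0.0470 with an estimated correlation). YAP and TAZ targets fell in 8 of 17, with CTGF at −2.39 ± 0.29 and CYR61 at −1.57 ± 0.30 (13 adjusted over the list alone; adjusted p = 1.16e-05, and adjusted p = 0.0778 with an estimated correlation). Fibroblast markers fell in 4 of 5 (adjusted p = 1.29e-09, and adjusted p = 4.51e-06 with an estimated correlation). Endothelial identity genes fell in 7 of 18, with the VEGF receptor FLT1 at −3.32 ± 0.17 and CD34 at −1.58 ± 0.33 (adjusted p = 1.13e-04, and adjusted p = 0.176 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 17 (16 adjusted over the list alone; adjusted p = 1.40e-06, and adjusted p = 0.176 with an estimated correlation).

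Further lists passed with CCM2 loss in HCMEC/D3. Tip cell genes had 1 member up and 7 down of 16 (adjusted p = 0.00104, 0.0321 with an estimated correlation). The endothelial to mesenchymal transition list had 1 up and 5 down of 20, with TAGLN at −3.65 and CDH2 at −2.07 (adjusted p = 0.00123, 0.0133 with an estimated correlation). The BMP and TGF-beta list had 2 up and 3 down of 14, passed as lower, and had a median of 0.02 against a mean of −0.63 (adjusted p = 0.0274, 0.0457 with an estimated correlation). The lists of Notch signalling (1 up, 3 down of 10), arterial, venous and lymphatic fate and epithelial markers (2 of 4 down) passed as lower at adjusted p = 0.0237, 0.0182 and 0.0276, and at adjusted p = 0.176, 0.176 and 0.108 with an estimated correlation. The KLF axis list passed as higher, with 5 up and 3 down of 19 (11 and 3 adjusted over the list alone; adjusted p = 0.0274, 0.176 with an estimated correlation). The members that fell included TIMP3 (−1.96) and ADAMTS1 (−1.78). The RhoA list did not pass, although MYL9 (−1.99) and RND3 (−1.42) fell. Limma called 1399 genes, 567 higher and 832 lower, with 375 and 392 genes without WT replicates 3 and 1, and 909 and 3005 without 2KO replicates 1 and 2.

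Of the 3 knockouts 3KO had the largest rise of KLF2 over WT (2.05 ± 0.20; 200.1 against 47.9 RPKM; limma, adjusted p = 1.42e-04), with KLF4 at 2.39 ± 0.26. THBD (4.03 ± 0.26) and NOS3 (2.96 ± 0.26) rose with them. The KLF axis list had 8 members up and 1 down of 19 (10 and 1 adjusted over the list alone; adjusted p = 1.58e-07, and adjusted p = 8.63e-04 with an estimated correlation). Among the largest rises were those of genes of stratified epithelia, the keratin KRT14 (5.32 ± 0.23) and the desmosomal plakophilin PKP1 (4.74 ± 0.16). They were followed by ANO4 (4.69 ± 0.22), SLAMF9 (4.52 ± 0.24), ARHGEF4 (4.52 ± 0.17), FAM83A (4.39 ± 0.24) and TRIML2 (4.33 ± 0.17). Among the lowest were FGG (−7.45 ± 0.22), CYBA (−7.34 ± 0.21), the decoy receptor TNFRSF6B (−6.05 ± 0.30), COL6A2 (−5.97 ± 0.29) and N-cadherin, CDH2 (−4.99 ± 0.21). The tight junction protein claudin-5, CLDN5, rose by 2.41 ± 0.27. Occludin, OCLN, fell (−2.26 ± 0.16).

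Interferon genes fell in 11 of 22 members with CCM3 loss in this line, with RSAD2 at −4.49 ± 0.49 (22 adjusted over the list alone; adjusted p = 9.98e-07, and adjusted p = 0.478 with an estimated correlation). Inflammation genes fell in 8 of 16, with CCL2 at −4.03 ± 0.36 (1 up and 11 down adjusted over the list alone; adjusted p = 4.74e-04, and adjusted p = 0.478 with an estimated correlation). Fibroblast markers fell in 4 of 5 (adjusted p = 9.38e-07, 4.73e-04 with an estimated correlation). The endothelial to mesenchymal transition list fell in 6 of 20 with 3 up, with TWIST1 at −2.86 (adjusted p = 0.00252, 0.0104 with an estimated correlation). Tip cell genes fell in 6 of 16 with 1 up (adjusted p = 3.96e-04, 0.010 with an estimated correlation). BMP and TGF-beta targets fell in 6 of 14 with 1 up, with BMP4 at −4.19 and BMP6 at 1.74 (adjusted p = 0.00418, 0.00707 with an estimated correlation). Basement membrane genes (2 up, 8 down of 22) and cholesterol synthesis genes (9 of 17 down) fell at adjusted p = 0.00418 and 0.00252, and at adjusted p = 0.333 and 0.582 with an estimated correlation. The lists of ECM proteases (5 up, 1 down of 13) and epithelial markers (of 4, KRT14 up and CLDN7 down) passed as higher, the latter with KRT14 as its only called rise, at adjusted p = 0.0127 and 0.00252, and at adjusted p = 0.0688 and 0.0145 with an estimated correlation. RHOB rose by 1.03 ± 0.16 and the formin DIAPH1 by 0.86 ± 0.18, while the myosin MYH10 fell (−1.78 ± 0.18). RHOA had 0.42 (adjusted p = 0.115), and the RhoA, SRF, junction, cell cycle and smooth muscle lists did not pass in any of the 3 knockouts. Limma called 1948 genes, 695 higher and 1253 lower, and quantile normalization gave 873 and 984. The count was 829 and 903 without WT replicates 3 and 1, and 1029 and 1067 without 3KO replicates 1 and 2.

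Compared with each other, the knockouts differed in KLF2, which was lower in 1KO than in 3KO (−1.27 ± 0.20, adjusted p = 0.00339) and in 2KO than in 3KO (−1.39 ± 0.20, adjusted p = 0.00223). Between 1KO and 2KO it had 0.12 (limma, adjusted p = 0.770). Against 2KO, 1KO had higher FBN2 (6.56 ± 0.23), FGG (5.67 ± 0.22) and FLT1 (5.27 ± 0.17) and lower CXCL12 (−5.93 ± 0.41), ARHGAP22 (−5.13 ± 0.15) and TMOD1 (−3.96 ± 0.51). In 1KO 9 of 18 endothelial identity genes were higher with 1 lower (adjusted p = 3.20e-12, 0.00628 with an estimated correlation). Against 3KO, 1KO had higher CYBA (6.62 ± 0.21), FGG (6.14 ± 0.22) and the amino acid transporter SLC6A15 (5.16 ± 0.20) and lower ARHGAP22 (−5.33 ± 0.15) and TRIML2 (−4.06 ± 0.17), with SMURF1 lower (−0.72, adjusted p = 0.0161). Against 3KO, 2KO had higher complement C3 (5.73 ± 1.04; 114 ± 124 RPKM, SD, n = 2, in 2KO, so its libraries differed widely) and glycophorin C, GYPC (5.16 ± 0.22), and lower FBN2 (−6.31 ± 0.23) and KRT14 (−5.28 ± 0.23). Of its epithelial markers 3 of 4 were lower (adjusted p = 9.04e-09, 1.20e-06 with an estimated correlation). Other lists higher in 1KO than in 2KO were tip cell genes (9 up, 1 down of 16), arterial, venous and lymphatic fate (5 of 8 up), ECM proteases (8 of 13 up), epithelial markers (4 of 4 up) and fibroblast markers (4 up, 1 down of 5), at adjusted p = 4.39e-06, 1.31e-07, 1.31e-07, 1.03e-05 and 0.00632, and adjusted p = 7.76e-04, 0.00184, 4.25e-05, 4.43e-04 and 0.0490 with an estimated correlation. Basement membrane genes (5 up, 1 down of 22), the mesenchymal transition list (5 up, 2 down of 20) and YAP targets (6 of 17 up) were higher at adjusted p = 0.0105, 0.0273 and 0.00632, and adjusted p = 0.311, 0.0549 and 0.296 with an estimated correlation. Glycolysis genes (4 of 20 down) and smooth muscle markers (2 of 5 down) were lower at adjusted p = 0.00438 and 0.0481, and adjusted p = 0.00184 and 0.0549 with an estimated correlation.

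In 1KO against 3KO tip cell genes were higher (7 up, 1 down of 16; adjusted p = 6.24e-07, and adjusted p = 2.86e-04 with an estimated correlation). So were interferon (6 of 22 up), inflammation (4 of 16 up), fibroblast (3 of 5 up), mesenchymal transition (3 up, 2 down of 20) and arterial, venous and lymphatic genes (4 up, 2 down of 8), at adjusted p = 4.24e-04, 0.0233, 0.0262, 0.0262 and 0.00648, and adjusted p = 0.611, 0.611, 0.137, 0.137 and 0.137 with an estimated correlation. The KLF axis list was lower (3 of 19 down; adjusted p = 0.0233, and adjusted p = 0.179 with an estimated correlation). In 2KO against 3KO ECM proteases (1 up, 6 down of 13) and the KLF axis list (2 up, 6 down of 19) were lower at adjusted p = 2.14e-05 and 7.17e-05, and adjusted p = 9.46e-04 and 0.0240 with an estimated correlation. Lower as well were endothelial identity genes (8 of 18), YAP targets (6 of 17), SRF targets (2 up, 6 down of 21), RhoA genes (1 up, 5 down of 29) and Notch genes (1 of 10), at adjusted p = 3.04e-06, 3.61e-04, 0.00570, 0.0205 and 0.0359, and adjusted p = 0.161, 0.247, 0.247, 0.264 and 0.264 with an estimated correlation. Higher were interferon (4 of 22) and inflammation genes (5 of 16), at adjusted p = 1.41e-04 and 4.38e-05, and adjusted p = 0.501 and 0.341 with an estimated correlation.

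Limma called 1292 genes between 1KO and 2KO (663 higher, 629 lower), 1697 between 1KO and 3KO (981 higher, 716 lower; 695 and 912 after quantile normalization) and 1325 between 2KO and 3KO (784 higher, 541 lower). The first was 633 and 644 without 1KO replicates 1 and 2 and 2099 without 2KO replicate 2. The second was 680 and 647 without 3KO replicates 1 and 2 and 742 without 1KO replicate 1, and the last 553 and 537 without 3KO replicates 1 and 2 and 2708 without 2KO replicate 2. In all 3 knockouts 118 genes rose and 352 fell, against 2.19 and 6.61 for independent lists of these sizes, and 64 were called in all 3 with mixed signs. They shared their WT libraries, so part of that excess may come from them.

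Fold changes of the same loss were then set side by side in both cell types, over 10827 genes tested in each. For CCM1 44 genes were called in both, against 16 for independent lists, and 32 had the same sign, among them KLF2, KLF4, THBD, NOS3, CMKLR1, SLCO2A1, SULF2, PHGDH and HMGCS1 (odds ratio 3.92; Fisher's exact test, two-sided, adjusted p = 1.37e-10 over 9 comparisons). For CCM2 84 genes were called in both against 45.7, 67 with the same sign (odds ratio 2.14, adjusted p = 3.72e-08), and for CCM3 63 against 26.7, 56 with the same sign (odds ratio 3.27, adjusted p = 2.90e-11). With the untreated HUVEC controls summed, 0, 1 and 2 genes were called in both for CCM1, CCM2 and CCM3, so these overlaps rest on calls that the controls decide. Genes are not independent replicates, and pairings of different losses gave odds ratios from 1.92 to 4.28. Across genes the correlation of fold changes was low, with a Pearson r of 0.0873, 0.216 and 0.272 and a Spearman correlation of 0.0450, 0.265 and 0.210 for CCM1, CCM2 and CCM3. Opposite calls included CXCR4, PGF and MALL for CCM1, TIMP3, ADAMTS1 and MYLK for CCM2 and DARC and ABCB1 for CCM3.

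The authors' deposited tables of HUVEC comparisons listed 506, 529 and 820 genes under a false discovery rate of 0.05 for CCM1, CCM2 and CCM3 without Y27632. Across genes, which are not independent, log fold changes in the authors' deposited tables correlated with those here at r = 0.909, 0.926 and 0.893. All 167, 559 and 241 calls here that the tables held had the same sign, and 141, 230 and 178 passed there. With Y27632 the authors' deposited tables held 69, 236 and 718 such genes, with r = 0.855, 0.871 and 0.716 against the treated control and 0.852, 0.906 and 0.732 against the untreated one, so which control was used there is not settled. For HCMEC/D3 the authors' deposited tables held 402, 380 and 692 genes, all above about 0.693 in absolute log fold change, with r = 0.933, 0.933 and 0.930 and slopes of 0.493, 0.460 and 0.518 against the log2 changes computed here. As 0.693 is the natural log of 2, the base of these tables is in doubt, although their headers say log2.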

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

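All the tests of explanations in this part were chosen only after the results they concern had been seen. In 6 pairs of results, every library of one cell type moved one way and every library of the other the opposite way under the same loss. The difference between the cell types was not tested in any of them. With CCM1 loss CXCR4 had −2.79 in HUVEC (11.2 to 13.9 against 92.2 to 92.5 CPM) and 1.71 in HCMEC/D3 (1.17 to 1.32 against 0 to 0.07 RPKM). PGF had −1.87 (67.7 to 107 against 362 to 368 CPM) and 1.17 (9.05 to 11.2 against 3.88 to 4.54 RPKM). With CCM2 loss MYLK had 0.97 (121 to 136 against 65.3 to 65.8 CPM) and −0.86 (13 to 24.1 against 32.2 to 32.8 RPKM). ADAMTS1 had 2.81 and −1.78, and TIMP3 5.73 (1.97 to 21.5 against 0.132 to 0.163 CPM) and −1.96 (6.15 to 9.54 against 27.3 to 35.8 RPKM). With CCM3 loss DARC had 5.61 (11.5 to 22.5 against 0.264 to 0.436 CPM) and −1.82 (0 against 1.04 to 1.53 RPKM). RPKM near 0 and CPM under 1 rest on few reads.

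The first pattern weighed was the shCCM3 pair of run A. Across 11627 genes its Y27632 difference correlated at r = −0.274 with the mean of the other pairs, which had r of 0.360 to 0.544 with theirs. An opposite response of cells without CCM3 was argued against by the other shCCM3 pair, in run B, at r = 0.516. Swapped labels of the run A pair would turn the sign as seen (r = −0.274). A swap was also predicted to give an r farther from 0 than that of the lowest other pair, 0.360. The size fell short of this, so the values do not decide it. A swap cannot be told apart from another difference of run A, since that run held this pair alone.

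The next pattern was the likeness of the untreated control libraries. Their BCV of 0.0225 lay far below the 0.149 of the closest other pair of one group from different runs, which argued against separate cultures that vary like the other groups. The same RNA sequenced in both runs would give a BCV near 0, and the value of 0.0225 is consistent with it. If so, the spread between control libraries would be technical, and p-values against them too small. No biological explanation was tested for it.

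The last pattern was the low interferon list in shCCM2 and shCCM3 cells. Its mean in the untreated libraries was 2.27 log2 units below the controls, and variation of the list between control libraries stays open, since the treated controls, both of run B, differed by 2.06. A list lower with loss of any CCM gene cannot be told apart from other causes, because shCCM1 libraries reached 7.47, above every control, while others lay below. A list lower with loss of CCM2 or CCM3 also stays open, as the highest of their libraries, at 3.97, lay above the lowest control at 3.88.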

How the results depend on the processing

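The fits with the controls summed, without run A, with construct and run as a replicate block and with any knockdown were chosen only after the results were seen. No named gene that passed the threshold in the main fit or in an alternative changed direction between them. The signs of genes near 0 that passed in neither were not counted. In addition, RLE scaling, pseudocounts of 0.1 and 1, no filter in HCMEC/D3 and quantile normalization left every count within 1.5 times. Depth limits low genes, the HUVEC tests of single losses missed most simulated changes of 2-fold, and no count of an untreated loss against the controls passed 4 when an untreated control library was left out or both were summed. Where an arm kept 1 library, it was assumed to vary like the other groups. Of the named genes, 119 of 123 kept their side of the threshold with DESeq2 and 4 passed newly. The share was 105 of 123 with only the compared libraries, 84 of 123 with no filter, 1026 of 1627 when 1 library was left out, and 22 of 123 with the controls summed. The cause of the changes below was not tested, except that fewer libraries give fewer degrees of freedom.

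With DESeq2 the counts for CCM1, CCM2 and CCM3 loss against control were 622, 1448 and 958 (edgeR 167, 575 and 245), those under Y27632 21, 173 and 774 (edgeR 0, 11 and 156), and the effect of Y27632 in shCCM1 41 (edgeR 0). The comparisons of CCM1 with CCM3, CCM2 with CCM3 and CCM1 with CCM2 gave 1581, 149 and 2018 (edgeR 668, 16 and 1171), the CCM2 hairpins 28 (edgeR 1) and the shared genes 203 (edgeR 39). DESeq2 also moved the share of higher calls, with 720 higher and 728 lower for CCM2 (edgeR 216 and 359) and 499 and 459 for CCM3 (edgeR 100 and 145). Likewise it gave 108 and 65 for CCM2 under Y27632 (edgeR 8 and 3) and 5 and 23 for the hairpins (edgeR 0 and 1). With only the compared libraries the counts were 902 for CCM2, 1068 for CCM3, 0 and 515 for CCM2 and CCM3 under Y27632, 1, 4 and 1 for CCM1 with CCM3, CCM2 with CCM3 and CCM1 with CCM2, 0 for the hairpins and 67 for the shared genes. Without a filter they were 1 and 39 for CCM1 and CCM2 under Y27632, 439, 26 and 748 between losses in the same order, and 3 for the hairpins, and with a filter of 1 CPM 26 for CCM2 with CCM3. With the untreated controls summed they were 0, 1 and 4 for CCM1, CCM2 and CCM3, 0 for the shared genes and 236 for any knockdown. Without run A they were 94 for CCM3, 2 for CCM3 under Y27632, and 10 and 4 for CCM1 and CCM2 with CCM3. The averaged Y27632 effect with construct and run as a replicate block called 501 genes without the run A pair. With an estimated correlation 30 list tests passed, against 127.

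Runs were not taken to pair samples, as no label says so. Deviations in one run still correlated above 0.1 in 10 of 21 pairs of HUVEC groups (r −0.150 to 0.766). Pairs with the nearly alike untreated controls cannot show this (r −0.020 to 0.020). The median BCV was 0.165 between treatments of one construct and run, against 0.268 in one group from different runs. With run as a replicate block 19 of 25 counts stayed within 1.5 times, and the others were 1304 for CCM2, 2 and 314 for CCM2 and CCM3 under Y27632, and 1378, 6 and 2270 between losses in the order above.

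With 1 library left out, counts ran from 0 to 138 for CCM1, 1 to 428 for CCM2, 4 to 105 for CCM3, 2 to 18 and 2 to 96 for CCM2 and CCM3 under Y27632, and 0 to 2 for Y27632 in shCCM1. They ran from 12 to 727, 4 to 169 and 30 to 1438 between losses, 0 to 1 for the hairpins, 206 to 720 for any knockdown and 0 to 44 for the shared genes. In HCMEC/D3 they ran from 337 to 1149 for 1KO, 375 to 3005 for 2KO and 829 to 1067 for 3KO. Between knockouts they ran from 647 to 1187, 537 to 2708 and 633 to 2099 for 1KO with 3KO, 2KO with 3KO and 1KO with 2KO. The other comparisons, each with 0 calls in the main fit, stayed at 0. Genes called in all 3 knockouts or in both cell types were not recounted with a library left out.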

Other observations

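The comparisons and tests in this part were chosen only after the data or the results they concern had been seen. Taken over both treatments, with treatment as a covariate, 17 knockdown libraries were compared with 4 control libraries. KLF2 was 403 ± 129 CPM (SD) against 133 ± 29.5, a rise of 1.60 ± 0.23 (edgeR, adjusted p = 3.89e-04), and KLF4 rose by 2.27 ± 0.30. CCM2L rose by 1.15 ± 0.22 (adjusted p = 0.00321), ITGB4 by 2.41 ± 0.25, the scaffold protein SLC9A3R2 by 2.09 ± 0.28, and the progenitor marker CD34 by 3.05 ± 0.70. The angiopoietin receptor TEK rose by 0.64 ± 0.19, HEG1 by 1.69 ± 0.32, the laminin chain LAMA5 by 0.94 ± 0.24 and the BMP target ID1 by 1.02 ± 0.19. The largest rises were those of IGFBP5 (5.77 ± 1.21; 142 ± 177 CPM, SD), CMKLR1 (4.73 ± 0.99), PI16 (4.49 ± 0.54), the urea transporter SLC14A1 (4.41 ± 0.81), CYP26B1 (4.19 ± 0.91) and KCNN4 (4.15 ± 0.78). The receptor KIT (−2.92 ± 0.54; 4.32 against 32.8 CPM), the TEK ligand ANGPT2 (−1.57 ± 0.36), COL12A1 (−1.35 ± 0.34), SNAI1 (−1.25 ± 0.23), the amino acid enzyme ASNS (−1.25 ± 0.21) and the chaperone HSPA5 (−0.49 ± 0.14) fell. The KLF axis list rose in 11 of 25 members (14 up and 2 down adjusted over the list alone; adjusted p = 7.34e-07, and adjusted p = 0.00890 with an estimated correlation). The junction list rose in 4 of 20 (adjusted p = 0.0293, and adjusted p = 0.283 with an estimated correlation). The lists of interferon (3 of 24 members called) and stress responses (4 of 19) passed as lower, at adjusted p = 2.55e-06 and 0.0359, and adjusted p = 0.526 for both with an estimated correlation, while the treated controls differed by 2.06 in the mean of the first. RHOA had 0.06, SMURF1 0.14 and MAP3K3 −0.04, and none was called. In all, 1042 of 15646 genes passed, 611 higher and 431 lower, 236 with the untreated controls summed, and 221, 206 and 511 without control replicate 1, control replicate 2 and control with Y27632 replicate 2. Of 60 splits 1, the real one, reached 1042 and the highest other 7, which argued against a chance split of independent libraries. The libraries are not all independent, though. The untreated controls were nearly alike (BCV 0.0225), and libraries of one construct and run resembled each other across treatments (median BCV 0.165), so control libraries that stand apart as a cluster for another reason are not excluded.

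In the Y27632 effect with pairs of one construct and run, 1 of the 8 fits that leave out a pair called genes. Without the shCCM3 pair of run A, chosen by its outcome, KLF2 fell (−0.72 ± 0.09), as did KLF4 (−0.90 ± 0.11), SLC9A3R2 (−0.70 ± 0.10), CLDN5 (−0.71 ± 0.17), HEG1 (−0.57 ± 0.13), DLL1 (−0.47 ± 0.11) and ADAM19 (−0.89 ± 0.14). Of the YAP and TAZ list, which did not pass, 3 of 17 members rose (adjusted p = 0.123, and adjusted p = 0.249 with an estimated correlation), CYR61 (1.39 ± 0.17), CTGF (1.45 ± 0.29) and AMOTL2 (0.48 ± 0.11). THBS1 (1.04 ± 0.14), ANGPT2 (1.14 ± 0.20), ESM1 (0.72 ± 0.17) and POSTN (1.74 ± 0.36) rose, as did the proliferation genes MKI67 (1.21 ± 0.18), BUB1 (1.13 ± 0.16) and RRM2 (1.11 ± 0.16). Of the cell cycle list 16 of 25 members rose (24 adjusted over the list alone; adjusted p = 5.65e-23, and adjusted p = 0.0297 with an estimated correlation). Of the KLF axis list 6 of 25 fell (1 up and 8 down adjusted over the list alone; adjusted p = 2.55e-06, and adjusted p = 3.25e-04 with an estimated correlation). Also lower were the lists of stress responses (3 of 19 members called), interferon (0 of 24) and Notch signalling (1 of 15), at adjusted p = 5.17e-06, 1.33e-04 and 0.0117, and adjusted p = 0.0367, 0.611 and 0.222 with an estimated correlation. No other list passed. The fit called 501 genes, 261 higher and 240 lower, and of 60 splits that exchange treated and untreated libraries within pairs 1, the real one, reached that count, with 1 gene in the highest other. The splits do not allow for the choice of the pair left out. The fall of KLF2 and KLF4 here follows in part from leaving out a pair in which they rose, so it tests no hypothesis on ROCK inhibition, and the fit with all 8 pairs called 0 genes.

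Other splits of the libraries were tried for further comparisons. Between CCM1 and CCM3 loss 1 of 10 splits, the real one, reached 668 genes and the highest other 0, but 10 splits are too few for a share under 0.05. Between CCM1 loss and CCM2 loss with its hairpins pooled, 1 of 35 reached 1204 and the highest other 199, which argued against a chance split. Between pooled CCM2 loss and CCM3 loss 3 of 35 reached the real 13. The highest, 132, set the 3 run C libraries against the rest, and another called 81, which points to sample structure. With the hairpins kept apart, that comparison called 6 genes with run as a replicate block. For the effect of Y27632 in pooled shCCM2 cells and for the averaged effect the real count was 0, which every split reaches, so the splits test nothing there. In the former the highest of 35 splits, 539, set run C against run B, beside 115 and 102 in the next. In the latter the highest of 40 called 23. HNRNPH2 fell with CCM3 loss in HUVEC (−1.54 ± 0.17) and was higher with CCM2 than with CCM3 loss (1.47 ± 0.15). It had −0.08 for CCM1 loss, −0.07 for CCM2 loss and −0.19 in 3KO, none of these 3 called. With 1 hairpin against CCM3, an effect of that hairpin on HNRNPH2 cannot be told apart from CCM3 loss.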
